A study of Homo sapiens with 2 samples.

How the data were processed

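RNA of single cells was measured in 2 libraries of human cerebral organoids, which are 3-dimensional cultures of brain-like tissue grown from pluripotent stem cells. Per the labels, both came from 1 wild-type line of induced pluripotent stem cells, the Thermofisher Human Episomal iPSC line (A18945), 1 library at culture day 93 and 1 at day 140. The titles gave these days, while the files of the day 93 library are labelled with day 90. The labels do not say how many organoids went into a library. The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell barcode, made with Cell Ranger 3.1.0 per the file headers. The submitters' processing notes also name bcl2fastq and the genome build hg38. The release of the gene annotation and the chemistry of the libraries were not given in the sources used here, nor was the use of strand in counting. The deposited counts were not normalised, and their barcodes had already been called as cells by software.

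The files held 6172 barcodes with 32598126 UMIs at day 93 and 4479 barcodes with 26477190 UMIs at day 140, over 33538 genes. Of these gene identifiers, 33456 (99.8%) were found in GENCODE v29 on GRCh38 (hg38), from which the coordinates were taken. Genes of the Y chromosome, XIST and TSIX (102 identifiers) were left out of all gene results. Barcodes with fewer than 500 detected genes (495 and 201) or more than 20% mitochondrial UMIs (1541 and 283) were left out. Likely doublets were scored against simulated sums of 2 cells of the same library, 2 per cell, by the number of simulated among the 61 nearest neighbours. The highest scores were removed, 0.8% of the remaining cells per 1000 barcodes, which was 223 cells (4.94%) at day 93 and 147 (3.58%) at day 140. The kept cells numbered 4295 (69.6% of barcodes) and 3954 (88.3%), with 25646498 and 23527175 UMIs, so the mitochondrial ceiling took a larger part of the day 93 library.

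Counts per 10000 UMIs of a cell were put on a log scale, and 2000 variable genes were scaled over both libraries. With 30 principal components and 15 neighbours, both libraries were clustered together with the Leiden algorithm at resolution 0.8 (seed 1). A cluster took the class with the highest mean log2 fold over all other cells among 24 marker lists. Only classes with at least 3 markers counted, each at least 2-fold higher and seen in at least 10% of the cluster's cells. Radial glia, outer radial glia and astrocyte clusters were joined as astroglia, and fibroblast and smooth muscle clusters as mesenchyme. These names rest on markers, so every class is called X-like. The marker lists were fixed beforehand, but the naming rule was set after the data had been seen. Set at the same stage was the step that clustered a group of cells again where markers of 2 unrelated classes averaged over 4-fold. A cluster with more markers of another class than of its own among its 10 leading genes stayed unnamed. Here the markers of all classes joined with its own counted as its own, as did general neuron markers for glutamatergic and GABAergic clusters. Unnamed cells made up 6.15% of the day 93 cells and 1.26% of the day 140 cells.

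For gene levels, UMIs were summed over all kept cells of a library, or over the cells of 1 class, and divided by their total to give CPM, levels scaled to the same total in both libraries. Ratios are log2 of day 140 over day 93, so a positive value is a higher level at day 140. Their 95% intervals are exact conditional binomial intervals, those of CPM exact Poisson intervals and those of shares exact Clopper-Pearson intervals. For a share of 0 cells, the limit given is 3 cells over the total. All of them cover counting error only. With 1 library per day there were no replicates, so no test was made and no p-value is given. Genes were called higher or lower by size alone, from 2-fold. A count of 0 was set to 3 counts in a ratio, which is then a bound. Counted genes had at least 50 UMIs over both libraries and at least 20 CPM in either whole library, or 50 CPM in either sum of a class. Classes with at least 50 cells in each library were compared, which left the glutamatergic-like, astroglia-like, dividing and mesenchyme-like cells.

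The named genes were the 12 highest and the 12 lowest log2 ratios in whole libraries and the 6 highest and 6 lowest in each compared class. Also named were up to 4 members of each gene list with the largest ratios of either sign, markers of a class, and list members that the text counts. Genes known only by a clone-based identifier were counted and not named, and some genes that fall under this rule are not reported here. For 41 gene lists, the median log2 ratio of the members with at least 10 CPM in either library was set against 10000 random lists of the same size matched on mean expression. The percentile among them describes these 2 libraries. For shares of cells with a UMI, every cell was thinned to 2251 UMIs, the lower of the 10th percentiles of the 2 libraries, which left out 430 and 380 cells. Filters, marker lists, gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

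On simulated counts for the whole libraries (6660 genes past the floor), all of 100 genes raised or lowered 3-fold were counted. No gene raised or lowered 1.5-fold and no unchanged gene was counted. These counts were drawn from 1 profile shared by both libraries and held counting error only. They do not gauge how many genes would differ 2-fold between libraries of the same day. In that simulation 95.4% of true ratios lay inside their interval. A list of 15 raised genes reached percentile 100 and a list of 15 unchanged genes percentile 63.2. In the day 140 library, 64.7% of 150 added doublets were among the top 300 scores, against 7.06% by chance. The filter removed only 147 cells there (3.58%), so 64.7% may overstate the part of doublets it caught, and some doublets will have remained. Alternatives covered the filters, doublets, resolution, scaling, clustering of each library alone, naming per cell, depth, expression floors and class weights. Added after seeing the data were a mitochondrial ceiling of 10% for gene ratios within classes and for lists, brain classes only, and glutamatergic-like cells without 1 shallow cluster. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.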

Results

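Single-cell RNA was measured in 2 libraries of cerebral organoids grown from 1 wild-type line of human induced pluripotent stem cells, 1 library at culture day 93 and 1 at day 140. The series concerns how cells and electrical activity develop together in such cultures, and its design sets these culture times against each other. The day 93 library held 6172 barcodes with 32598126 UMIs, and the day 140 library held 4479 barcodes with 26477190 UMIs. After filtering, 4295 and 3954 cells remained, with a median of 4779 UMIs and 2017 genes per cell at day 93 and of 4565.5 UMIs and 1944 genes at day 140. The median mitochondrial share of kept cells was 9.20% at day 93 and 7.40% at day 140. There were no replicates, so a difference between the days cannot be told apart from one between the libraries, culture batches or organoids. Intervals are 95% intervals and cover counting error only.

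The first question was which kinds of cells made up the organoids at each day. GABAergic neuron-like cells, named from GAD1, GAD2 and the DLX genes of inhibitory neurons, were 9 of 4295 cells at day 93 (0.210%, interval 0.0959 to 0.397%) and 1495 of 3954 at day 140 (37.8%, 36.3 to 39.3%). Glutamatergic neuron-like cells, the excitatory neurons of the cortex, were 50.2% of cells (48.6 to 51.7%) at day 93 and 23.0% (21.7 to 24.4%) at day 140. Intermediate progenitor-like cells, which divide to give excitatory neurons and carry EOMES, were 8.45% (7.64 to 9.32%) and 0.759% (0.512 to 1.08%). Retina-like cells with the photoreceptor genes RCVRN and CRX were 7.29% (6.53 to 8.11%) and 0.632% (0.410 to 0.932%). Astroglia-like cells, which join radial glia, outer radial glia and astrocytes, were 20.2% (19.04 to 21.5%) and 19.04% (17.8 to 20.3%).

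Dividing cells were 4.12% (3.55 to 4.76%) of the day 93 cells and 13.0% (11.97 to 14.1%) of the day 140 cells. Mesenchyme-like cells, with collagen genes such as COL1A1 and COL3A1, were 2.77% (2.30 to 3.31%) and 2.83% (2.34 to 3.40%). Choroid plexus-like cells, with the transthyretin gene TTR, were 0.629% (0.415 to 0.913%) and 0.202% (0.0874 to 0.398%). Pigment cell-like cells (30 cells, 0.759%) and epithelium-like cells (27 cells, 0.683%, 0.450 to 0.992%) were named at day 140. Of the 4295 day 93 cells, 0 were in either class, which allows a share of up to 0.0698%. With a class per cell, 116 day 93 cells (2.70%) were epithelium-like and 20 (0.466%) pigment cell-like. That setting gives every cell a class, however weak its markers. All epithelium markers together had 162 UMIs in the kept day 93 cells, so these cells need not be epithelium. The astroglia-like difference (-1.19 points) and the dividing difference (8.88 points) depended on the settings. The former ran from -12.6 points with cells thinned before clustering to 7.36 points with at least 1000 genes per cell, and at both ends more cells were unnamed (21.2% of day 140 cells in the former and 16.2% of day 93 cells in the latter). The latter was -1.86 points with each library clustered alone and 0.178 points with a mitochondrial ceiling of 10%. With each library clustered alone, the glutamatergic difference was -17.8 points in place of -27.1 and the retina difference -3.64 in place of -6.66. With the ceiling of 10%, choroid plexus-like and pigment cell-like cells were named in neither library, the epithelium difference was 0.293 points, with 20 of 2600 day 93 cells in that class, and the mesenchyme difference was 1.69 points.

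**Figure D1:**
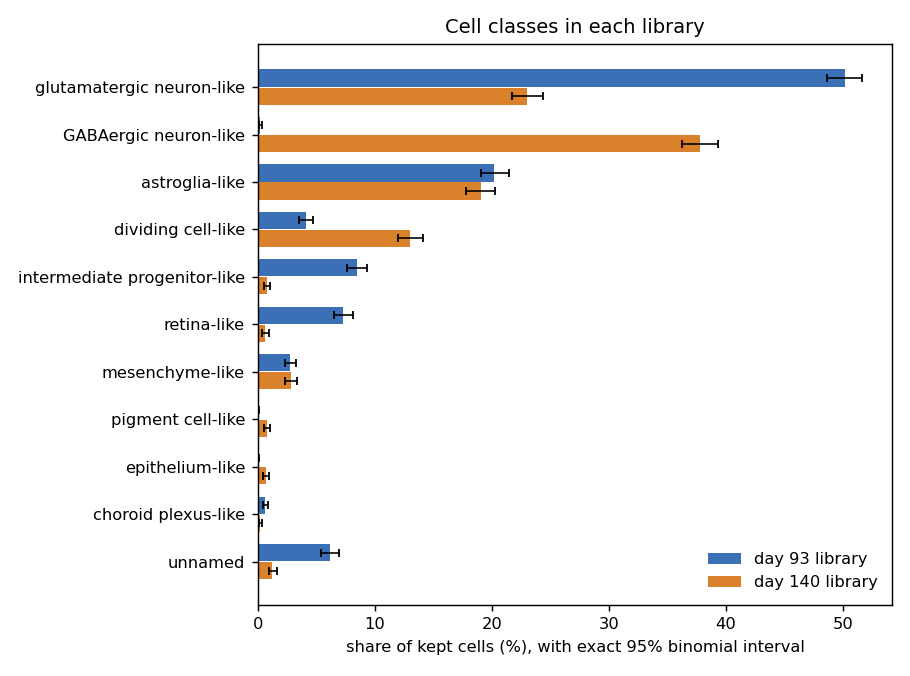
Share of kept cells (%) in each marker-named class at day 93 (blue) and day 140 (orange), with exact 95% binomial intervals as error bars, which cover counting error only. The GABAergic bar is 0.210% at day 93 and 37.8% at day 140, and the glutamatergic bar 50.2% and 23.0%.

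The glutamatergic-like and astroglia-like cells were held mainly by different clusters in the 2 libraries, and a cluster mostly of 1 library may be that library, not a type. The GABAergic-like cells lay in clusters 1 (8 day 93 and 1386 day 140 cells) and 16 (1 and 109). The glutamatergic-like cells of day 93 lay mainly in clusters 2, 6, 8 and 15 (1182, 443, 373 and 150 cells), and those of day 140 in clusters 5 and 6 (772 and 127 cells). The astroglia-like cells of day 93 lay in cluster 3 (795 cells, radial glia-like) and those of day 140 in cluster 4 (729 cells). The naming rule made cluster 4 outer radial glia-like, while its 10 leading genes held HOPX of that class beside OLIG1 and the astrocyte markers AQP4, GFAP and S100B. Dividing cells lay in cluster 9 (168 and 185 cells), led by mitotic genes, and in cluster 10 (9 and 329), led by genes of DNA replication. The mesenchyme-like cells formed 1 cluster (119 and 112 cells), and the intermediate progenitor-like cells 1 cluster (363 and 30). Among unnamed cells, cluster 11.2 (50 and 4) shared the leading genes CRABP1 and RAX, a retina marker, with retina-like cluster 11.1. Cluster 14 (194 and 31) shared CRABP1 with it, and cluster 11.3 (20 and 15) was set aside from the retina class. The retina-like shares may thus leave out related cells.

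The next question was which genes differed most between the whole libraries. Of 7049 genes past the expression floor, 252 were at least 2-fold higher and 266 at least 2-fold lower at day 140. Apart from DES, the 12 highest ratios belonged to genes known from liver, gut or other epithelia. SPINK1 (ENSG00000164266, chromosome 5, 147824568 to 147831786), which encodes a trypsin inhibitor, had 0.039 CPM (1 UMI) at day 93 and 113 CPM at day 140, a log2 ratio of 11.50 (9.02 to 16.80). SERPINA1 (ENSG00000197249, chromosome 14, 94376747 to 94390693), the gene of alpha-1 antitrypsin, went with it at 0.078 and 222 CPM, a log2 ratio of 11.48 (9.62 to 14.52). ALB (ENSG00000163631, chromosome 4, 73397114 to 73421412), the serum albumin gene, had 0.117 and 214 CPM (10.84, 9.29 to 13.12).

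Of the other epithelial genes, OLFM4 (9.66) and the keratin gene KRT8 (9.002) were higher by the log2 ratio given. CLDN4 (9.74, 7.25 to 15.04), GPX2 (9.62, 7.14 to 14.93) and HP (9.01, 7.46 to 11.29) rested on 1, 1 and 3 UMIs at day 93. APOA2, FABP1 and AMBP had no UMI at day 93, so their log2 ratios were at least 9.98, 9.37 and 9.08. Except for CLDN4, GPX2 and KRT8, these genes were among the 10 that led the epithelium-like cluster. That cluster held 27 day 140 cells with a median of 27309 UMIs, so a few deep cells weigh on these ratios. DES (ENSG00000175084, chromosome 2, 219418377 to 219426739), which encodes the muscle filament desmin, had 0.078 and 79.4 CPM (9.99, 8.14 to 13.04). Below these 12 genes stood GABAergic markers, with 11 of 11 measured members at least 2-fold higher and a median of 7.37. GAD2 (ENSG00000136750, chromosome 10, 26216307 to 26304558), a GABA-synthesising enzyme, had 1.91 and 315 CPM, and DLX5 (ENSG00000105880, chromosome 7, 97020392 to 97024950), a transcription factor of inhibitory neurons, 0.858 and 158 CPM.

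Lowest of all was NNAT (ENSG00000053438, chromosome 20, 37521206 to 37523693), an imprinted gene for the membrane protein neuronatin, with 63.5 CPM (1629 UMIs) at day 93 and 0.128 CPM (3 UMIs) at day 140. Its log2 ratio was -8.96 (-11.24 to -7.41). GPR22 (ENSG00000172209, chromosome 7, 107470018 to 107475659), an orphan receptor gene, had 63.0 and 1.62 CPM (-5.29). NTS (ENSG00000133636, chromosome 12, 85874295 to 85882992), the neurotensin gene, had 395 and 12.1 CPM (-5.03, -5.20 to -4.86). CRYM (ENSG00000103316, chromosome 16, 21238874 to 21303083), a thyroid hormone-binding protein of deep cortical layers, had 90.9 and 2.85 CPM (-5.00). EMX1 (ENSG00000135638, chromosome 2, 72916260 to 72936071), a transcription factor of the dorsal forebrain, had 71.0 and 6.29 CPM (-3.50). The photoreceptor genes RCVRN (-5.08), PDE6H (-4.06) and AIPL1 (-3.85) and the gene TRH (-5.20) are among the leading genes of retina-like clusters. CRABP1 (-3.48) is among those of a retina-like cluster and of unnamed clusters 11.2 and 14. NEFL (-4.04), which encodes neurofilament light chain, and IGSF21 (-3.57) led glutamatergic-like clusters of day 93, as did GPR22, NTS and CRYM. With brain classes only, an alternative added later, 198 of 6934 genes were at least 2-fold higher and 270 lower. The 12 highest genes then had 6 to 71 UMIs each at day 140, with SERPINA1 at 2.83 CPM and ALB at 3.59 CPM, so their ratios rest on cells outside these classes. KRT8 was then at 2.22 (0.628 to 4.23), AMBP at least 0.970 and PDE6H at -0.62 (-2.88 to 1.46).

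**Figure D2:**
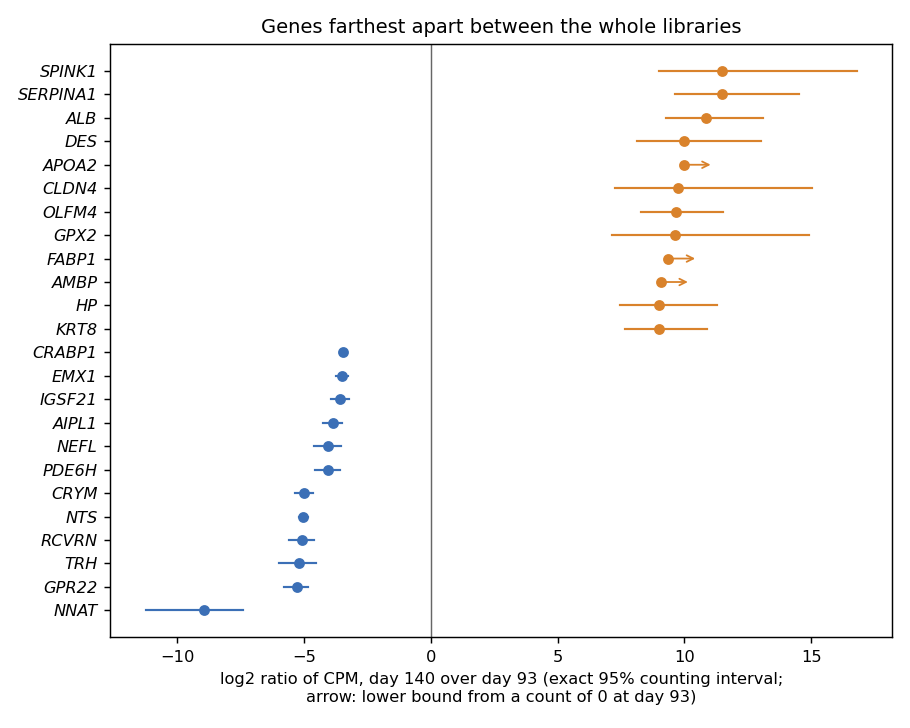
Log2 ratio of CPM, day 140 over day 93, in whole libraries for the 12 highest and 12 lowest named genes, with exact 95% counting intervals as bars. Arrows mark APOA2, FABP1 and AMBP, which had 0 UMIs at day 93 and are lower bounds; the points run from 11.50 for SPINK1 to -8.96 for NNAT.

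Within the glutamatergic-like cells (2154 and 910 cells; clusters 2, 6, 8 and 15 against 5 and 6), 116 of 3634 genes were at least 2-fold higher at day 140 and 117 lower. NR2F2 (ENSG00000185551, chromosome 15, 96325938 to 96340263), a nuclear receptor known from caudal and ventral forebrain, had 30.04 CPM at day 93 and 693 CPM at day 140, a log2 ratio of 4.53 (4.36 to 4.70). Its antisense gene NR2F2-AS1 (ENSG00000247809, chromosome 15, 96110040 to 96327361), which overlaps it, had 0.0957 (1 UMI) and 70.3 CPM (9.52, 7.03 to 14.83). UMIs of this pair may be mixed, since the use of strand in counting was not given. FST (4.03), which encodes the activin-binding protein follistatin, and PID1 (3.20) were also higher, as were BEX5 (3.62) and KLHL13 (3.52), which lead the day 140 cluster 5. Lower were CRYM (193 and 2.89 CPM, -6.06, -6.97 to -5.28), GPR22 (-5.65), NTS (-4.03), VSNL1 (-4.02) and LPL (-3.54), all of them among the leading genes of the day 93 clusters 8 or 15. FEZF2, a transcription factor of deep-layer projection neurons, had 109 and 8.90 CPM (-3.61). At 2251 UMIs per cell, NR2F2 was seen in 7.39% of glutamatergic-like cells at day 93 and 69.7% (66.4 to 72.9%) at day 140, and at full depth in 12.6% and 81.1%, with medians of 4344.5 and 4635.5 UMIs. No class was taken to lack NR2F2, since thinned cells of every large class held it.

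Within the astroglia-like cells (869 and 753 cells; cluster 3 against cluster 4), 95 of 3291 genes were at least 2-fold higher at day 140 and 163 lower. Genes of inhibitory neurons and their progenitors were among the highest ratios. DLX1 (ENSG00000144355, chromosome 2, 172084740 to 172089677) had 0.337 CPM (2 UMIs) at day 93 and 136 CPM at day 140, a log2 ratio of 8.65 (6.80 to 11.70). DLX2 (ENSG00000115844, chromosome 2, 172099439 to 172102900) followed at 8.004 (6.45 to 10.28) and GAD2 at 7.96 (6.41 to 10.24). The oligodendrocyte precursor genes OLIG1 and PDGFRA were higher too. OLIG1 (ENSG00000184221, chromosome 21, 33070144 to 33072420), a leading gene of cluster 4, had 12.6 and 233 CPM (4.21, 3.87 to 4.56). PDGFRA (ENSG00000134853, chromosome 4, 54229097 to 54298247), the platelet-derived growth factor receptor, had 0 and 61.6 CPM, at least 6.93 in log2. KCNIP4, a potassium channel subunit, had 3.87 and 70.8 CPM (4.19). Lower were EMX1 (84.0 and 3.30 CPM, -4.67), NTS (-5.30) and NEUROG2 (ENSG00000178403, chromosome 4, 112513516 to 112516172; 117 and 7.81 CPM, -3.91), a proneural factor of the dorsal forebrain. CDON (-4.19), a leading gene of cluster 3, was lower, and so were the cell-cycle genes SPC25 (-4.51) and RRM2 (-4.18), which stood at -1.84 and -2.18 with a class per cell. NTS led a glutamatergic-like cluster of day 93, so RNA of neuron-like cells may add to its day 93 level, which was not tested.

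The shares of astroglia-like cells with a UMI were read beside those of the glutamatergic-like cells, which should lack these genes. Thinned, GAD2 was seen in 0.119% of astroglia-like cells at day 93 and 16.9% (14.3 to 19.8%) at day 140, and at full depth in 0.345% and 25.4%. In the glutamatergic-like cells it was seen in 0% (up to 0.162%) and 1.55% (0.802 to 2.69%), and at full depth in 0% and 4.29%. OLIG1 was seen in 1.43% and 31.3% (27.9 to 34.7%) of thinned astroglia-like cells, and in 2.30% and 49.3% at full depth. PDGFRA was seen in 0% (up to 0.357%) and 11.4% (9.17 to 13.9%), and in 0% and 24.2% at full depth. In glutamatergic-like cells OLIG1 was seen in 0% and 0.387%, and PDGFRA in 0.162% and 3.22%. PDGFRA was also seen in 7.88% (6.47 to 9.50%) of thinned day 140 GABAergic-like cells and in 11.1% at full depth (median 3393 UMIs). Median depths were 6243 and 6480 UMIs in astroglia-like cells and 4344.5 and 4635.5 in glutamatergic-like cells.

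Within the dividing cells (177 and 514 cells; cluster 9 against clusters 9 and 10), 142 of 3423 genes were at least 2-fold higher at day 140 and 143 lower. The genes at the top were again those of inhibitory neurons. GAD2 had 1.29 CPM (2 UMIs) at day 93 and 674 CPM at day 140, a log2 ratio of 9.03 (7.18 to 12.08). DLX1 (8.18, 6.32 to 11.23), the calretinin gene CALB2 (7.23, 5.37 to 10.28) and SP9 (6.69, 4.83 to 9.74) had 2 UMIs each at day 93 and DLX6 (6.65, 4.16 to 11.96) had 1. DLX5 (6.46) was higher as well. At the bottom were genes of excitatory progenitors and neurons. EOMES (ENSG00000163508, chromosome 3, 27715949 to 27722711) had 368 and 13.1 CPM (-4.82, -5.25 to -4.41), NEUROG2 276 and 3.63 CPM (-6.25), and EMX1 83.2 and 0.242 CPM (1 UMI; -8.43, -13.74 to -5.92). NEUROD6 (-4.90), SSTR2 (-5.03) and CRABP1 (-5.37) were also lower, the first pair at -3.32 and -3.74 with doublets kept. In thinned dividing cells GAD2 was seen in 0.588% at day 93 and 62.7% (58.4 to 67.0%) at day 140, and EOMES in 37.6% and 1.57%. At full depth (medians 8102 and 7119.5 UMIs) these shares were 1.13% and 76.1% for GAD2 and 46.3% and 5.84% for EOMES. For comparison, 1.55% of thinned glutamatergic-like cells of day 140 (median 4635.5 UMIs; 4.29% at full depth), which should lack GAD2, held a UMI of it. In GABAergic-like cells of day 140, which should lack EOMES, 0.703% held a UMI thinned and 1.07% at full depth (median 3393 UMIs).

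Within the mesenchyme-like cells (119 and 112 cells of 1 cluster), 299 of 3043 genes were at least 2-fold higher at day 140 and 232 lower. DES, MYH11 and MYLK, all known from smooth muscle, were among the 6 highest ratios. DES had 0.741 CPM (1 UMI) at day 93 and 1010 CPM at day 140, a log2 ratio of 10.41 (7.93 to 15.72). MYH11 (ENSG00000133392, chromosome 16, 15703172 to 15857033), smooth muscle myosin, had 0.741 and 389 CPM (9.04, 6.55 to 14.34), and MYLK, myosin light chain kinase, 3.71 and 1294 CPM (8.45, 7.22 to 10.07). The transcription factor genes PITX1 (6.75, 4.24 to 12.06) and MEIS1 (6.23, 3.71 to 11.55) and the hedgehog-binding protein gene HHIP (6.35, 3.84 to 11.67) each had 1 UMI at day 93. CRABP1, a retinoic acid-binding protein, had 413 and 0.638 CPM (1 UMI; -9.34, -14.65 to -6.85). ALDH1A2 (-6.30, -11.63 to -3.78), which makes retinoic acid, and COL26A1 (-6.41, -11.73 to -3.88) had 1 UMI at day 140. LAMC3 (-5.85, -8.91 to -3.96) and SLC7A14 (-5.82, -8.88 to -3.93) had 2. NNAT had 289 and 0 CPM, at most -7.24 in log2. With a class per cell MYH11 was at 6.98, MEIS1 at 2.04 and CRABP1 at -4.69.

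The third question was whether groups of genes fixed beforehand stood apart. Each list is described by the median log2 ratio of its measured members and by the percentile of that median among 10000 matched random lists. Medians beyond the central 95% of the random lists are called above or below the random range. In whole libraries 8 of 38 lists with at least 3 measured members lay above it and 18 below.

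Genes of the excitable membrane had lower medians in whole libraries. The voltage-gated potassium channels had a median of -0.51 (10 measured, 2 at least 2-fold higher and 4 lower; percentile 0.4), with the subunit gene KCNIP4 at 3.19 and KCNMA1, a calcium-activated channel, at -1.75. The voltage-gated calcium channels had -0.51 (9 measured, 0 higher and 1 lower; percentile 0.285), with CACNA1A at 46.3 and 7.78 CPM (-2.57). The inward rectifier and two-pore potassium channels had -0.65 (5 measured, 0 higher and 2 lower; percentile 0.585), led by KCNK12 (-1.84). The voltage-gated sodium channels had -0.30 (5 measured, 1 higher and 2 lower; percentile 7.73, within the random range), with SCN1A at 1.30 and SCN3B at 106 and 28.4 CPM (-1.90). Among transmitter receptors, the AMPA and kainate receptors had -0.56 (7 measured, 0 higher and 1 lower; percentile 0.25), with the auxiliary subunit gene CNIH2 at -1.28. The GABA-A receptors had -0.28 (6 measured, 0 higher and 2 lower; percentile 7.6). The HCN channels, NMDA receptors and metabotropic glutamate receptors had fewer than 3 measured members, with PEX5L at -2.30, HCN3 at 0.08, GRIN2B at -0.99, GRM5 at -2.30 and GRM3 at -0.998. With each compared class weighted equally, which leaves out GABAergic-like cells, the calcium channel median was 0.23 and the inward rectifier and two-pore median 0.37. The potassium channel median was then -0.04 and the AMPA and kainate median -0.02, and all 4 calls ended.

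Within the glutamatergic-like cells the same channels and receptors mostly lay within the random range. The medians were 0.14 for the voltage-gated sodium channels (percentile 60.7), -0.12 for the voltage-gated potassium channels (10.1), 0.09 for the voltage-gated calcium channels (55.8), 0.20 for the AMPA and kainate receptors (80.6) and -0.21 for the GABA-A receptors (5.44). Single members differed, with KCNIP4 at 3.80, KCNB2 at -2.99, GABRG3, a leading gene of cluster 5, at 2.04, CACNA1A at -1.55, SCN1A at 1.36 and SCN3B at -1.01. The inward rectifier and two-pore potassium channels had 0.64 (5 measured, 2 higher and 1 lower; percentile 99.4), with KCNK2 at 1.67, KCNJ3 at 1.09 and KCNK12 at -1.27. With a floor of 1 CPM that median was -0.71. In astroglia-like cells the voltage-gated potassium channels had -1.38 (7 measured, 2 higher and 4 lower), which was -0.25 and within the random range with a floor of 1 CPM.

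The presynaptic and postsynaptic lists lay below the random range in whole libraries, with most of their members within 2-fold. The list of presynaptic vesicle release had a median of -0.81 (23 measured, 0 higher and 8 lower; percentile 0), with SNCB at -2.74, the calcium sensor gene SYT4 at 160 and 33.6 CPM (-2.25) and SNAP25, a core fusion protein, at -1.51. It was also below the random range in astroglia-like (-0.76), dividing (-1.52), glutamatergic-like (-0.20) and mesenchyme-like cells (-1.12). RNA of neuron-like cells may add to the values of the other classes, which was not tested for this list. In the glutamatergic-like cells 5 of 23 members were lower, among them SYT1 at 736 and 297 CPM (-1.31), and the list lay within the random range there with the mean over cells (-0.09) or a mitochondrial ceiling of 10% (-0.12). The list of postsynaptic scaffold and adhesion had -0.37 in whole libraries (21 measured, 2 higher and 3 lower; percentile 0.02), with NRXN3 at 2.47, LRRTM3 at 2.38 and NLGN1 at -1.40. It had 0.17 (percentile 83.2) in the glutamatergic-like cells, and 0.17 in whole libraries with classes weighted equally. In dividing cells it had -0.45. The list of GABA synthesis, transport and chloride balance had 0.05 (9 measured; percentile 63.2), with GAD2 at 7.37, GAD1 at 5.26 and SLC32A1, the vesicular GABA transporter, at 4.52 against GABBR2 at -1.55.

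The lists of cortical projection neurons lay below the random range in whole libraries and those of interneurons above it. The list of glutamatergic identity and transport had -0.79 (4 measured, 0 higher and 2 lower; percentile 0.26), with the vesicular glutamate transporter SLC17A7 at 50.9 and 10.5 CPM (-2.27). The deep-layer projection neuron list had -0.88 (9 measured, 0 higher and 4 lower; percentile 0), with CRYM at -5.00 and FEZF2 at -3.00. The upper-layer projection neuron list had -1.24 (11 measured, 1 higher and 6 lower; percentile 0), with RORB at -2.42, MEF2C at -2.03 and POU3F2 at 1.13. The newborn neuron list had -0.72 (11 measured, 0 higher and 3 lower; percentile 0), led by NEUROD4 (-3.39), and the list of neuron cytoskeleton and axon -0.67 (13 measured, 0 higher and 3 lower; percentile 0), led by NEFL and NEFM (-1.77). The list of interneuron subtypes and neuropeptides had 2.09 (5 measured, 3 higher and 1 lower; percentile 100), with CALB2 at 2.14 and 97.3 CPM (5.50), TAC3 at 2.55 and NPY at 2.09 against RELN at -1.18. The list of ganglionic eminence origin had 1.32 (11 measured, 7 higher and 0 lower; percentile 100), with SP9 at 8.28, SCGN at 7.85, GSX2 at least 8.07 and NR2F2 at 58.7 and 396 CPM (2.76). With classes weighted equally, the upper-layer median was 0.17 and that of glutamatergic identity and transport -0.33, both within the random range. The interneuron median was 0.46 and within the random range with a floor of 1 CPM.

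Within the glutamatergic-like cells the deep-layer projection neuron list had -0.82 (9 measured, 0 higher and 4 lower), with LDB2 at -2.84 and NFIB at -1.66 beside CRYM and FEZF2, while TBR1 stood at 0.61 and LMO3 at 0.93. The upper-layer projection neuron list had -0.50 (11 measured, 1 higher and 5 lower), with INHBA at -2.09, POU3F2 at 1.80 and CUX2 at 0.84. Interneuron subtypes and neuropeptides (2.69, 4 measured) and ganglionic eminence origin (1.197, 5 measured) lay above the random range there. A UMI of GAD2 was seen in 1.55% of these cells at day 140 when thinned, so RNA of GABAergic-like cells may add to both medians. In the second list NR2F1, a nuclear receptor of caudal cortex, had 238 and 1210 CPM (2.35), and MEIS2 stood at 1.197 and FOXP1 at -2.72. Ganglionic eminence origin also lay above the range in astroglia-like (0.46, 4 of 11 higher and 1 lower; GSX2 at least 6.42, SP8 -4.14) and dividing cells (0.56). The newborn neuron list lay below it in both of these classes (-1.13 and -1.20), and interneuron subtypes and neuropeptides had 3.95 in dividing cells. GABA synthesis, transport and chloride balance had -0.45 in astroglia-like cells (1 of 7 higher and 2 lower) and lay within the range. Below it were also glutamatergic identity and transport (-0.78) and the deep-layer list (-0.93) in astroglia-like cells. In mesenchyme-like cells GABA synthesis, transport and chloride balance (-0.86), the deep-layer list (-0.62), neuron cytoskeleton and axon (-0.74) and ganglionic eminence origin (-0.49) were below it. Above it there were voltage-gated potassium channels (2.83, 3 measured) and voltage-gated calcium channels (1.10), the latter at -0.66 with a floor of 1 CPM. RNA of neuron-like cells may add to the neuronal lists in astroglia-like and mesenchyme-like cells, which was not tested.

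Of the glial lists, astrocyte maturation and oligodendrocyte lineage lay above the random range in whole libraries and the ventricular radial glia programme below it. The astrocyte maturation list had a median of 0.66 in whole libraries (16 measured, 5 higher and 1 lower; percentile 100), with the angiotensinogen gene AGT at 2.22, the water channel gene AQP4 at 1.90, the gap junction gene GJA1 at 1.73 and CRYAB at 1.70. In astroglia-like cells it had 0.58 (18 measured, 6 higher and 0 lower), with GJA1 at 2.85, NTRK2 at 2.80, AGT at 2.54 and AQP4 at 2.01, of which NTRK2 and AQP4 lead cluster 4. The oligodendrocyte lineage list had 2.21 (5 measured, 3 higher and 0 lower; percentile 100), with OLIG1 at 4.03 and OLIG2 at 3.45, and 3.67 in astroglia-like and 3.16 in dividing cells. With classes weighted equally its median was 0.46 and within the random range. The outer radial glia programme had -0.02 (10 measured; percentile 39.7), and -0.73 in dividing cells. The ventricular radial glia programme had -0.22 in whole libraries (14 measured, 3 higher and 1 lower; percentile 0.62), the same in astroglia-like cells, and -1.19 in dividing cells, where the dorsal factor gene LHX2 stood at -3.54. It had 0.73 in glutamatergic-like and 0.59 in mesenchyme-like cells. With brain classes only it lay within the range in whole libraries (-0.09). Astrocyte maturation lay below the range in mesenchyme-like cells (-0.64).

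Cell cycle genes differed little in whole libraries. The list of cell cycle S phase had -0.06 (20 measured, all within 2-fold; percentile 27.1) and that of cell cycle G2 and M phase 0.32 (20 measured, 1 higher; percentile 99.97), with CENPF at 1.13. The latter was -0.65 with classes weighted equally. MKI67, a mark of dividing cells, was seen in 8.72% of thinned cells at day 93 and 10.2% at day 140 (12.9% and 13.1% at full depth, medians 4779 and 4565.5 UMIs), against 0.937% of thinned GABAergic-like cells of day 140 (1.47% at full depth, median 3393 UMIs). Within classes these lists went both ways. In astroglia-like cells S phase had -1.49 (17 of 20 lower) and G2 and M phase -2.39 (17 of 18 lower), and the day 93 cluster 3 was led in part by the replication gene PCLAF. In dividing cells S phase had 1.34 (15 of 20 higher) and G2 and M phase -0.59 (4 of 20 lower), and the S-phase cluster 10 was nearly all from day 140. In mesenchyme-like cells both were higher (1.09 and 1.92), with MKI67 seen in 2.61% and 2.73% of thinned cells (4.20% and 6.25% at full depth), and S phase had 0.40 in glutamatergic-like cells. With each library clustered alone, dividing cells were 15.1% at day 93 and 13.3% at day 140, in place of 4.12% and 13.0%. The medians of astroglia-like and dividing cells may thus rest in part on which class held the cycling cells of each library.

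The cholesterol synthesis list lay below the random range in whole libraries and in each compared class. Its median was -0.92 in whole libraries (17 measured, 0 higher and 7 lower; percentile 0). HMGCS1 (ENSG00000112972, chromosome 5, 43289395 to 43313512), the enzyme at the start of the mevalonate pathway, had 298 and 122 CPM (-1.28). STARD4 (ENSG00000164211, chromosome 5, 111496033 to 111512590), a sterol carrier, had 32.7 and 10.2 CPM (-1.68), and MSMO1 (-1.24), a late enzyme, was lower too. In glutamatergic-like cells the median was -1.53 with 14 of 17 lower, STARD4 at 39.2 and 3.34 CPM (-3.55) and FDFT1 at 309 and 74.4 CPM (-2.06). It was -1.12 in mesenchyme-like cells (10 of 17 lower), -0.71 in dividing cells (3 of 17) and -0.40 in astroglia-like cells (2 of 17). FDPS, which has processed pseudogenes, was the exception and stood at 0.30, 0.49 and 0.74 in whole libraries, astroglia-like and dividing cells.

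The glycolysis and hypoxia list lay below the range in the same places. In whole libraries it had -0.58 (24 measured, 1 higher and 7 lower; percentile 0), with PDK1 at -1.81, HK2 at -1.79, VEGFA at -1.46 and BNIP3 at -1.42. It had -0.88 in astroglia-like cells (10 of 23 lower; VEGFA -2.05), -0.43 in dividing cells (5 of 16; VEGFA -2.83), -0.42 in glutamatergic-like cells (4 of 17) and -0.36 in mesenchyme-like cells (5 of 25). LDHA (ENSG00000134333, chromosome 11, 18394388 to 18408425), lactate dehydrogenase, went the other way, with 24.7 and 168 CPM (2.77) in whole libraries and 30.4 and 903 CPM (4.89) in mesenchyme-like cells. LDHA has many processed pseudogenes, so its level is uncertain. The nuclear genes of mitochondrial oxidative phosphorylation had -0.09 in whole libraries (30 measured, all within 2-fold; percentile 0.92), -0.20 in glutamatergic-like and -0.34 in mesenchyme-like cells. The mitochondrial genome list had -0.23 (13 measured; percentile 0.19), -0.21 and -0.55 in the same order. The median mitochondrial share of cells was lower at day 140 in these classes, at 8.87% and 7.41% in glutamatergic-like and 11.7% and 7.10% in mesenchyme-like cells. The cytosolic ribosomal proteins had 0.00 (33 measured, all within 2-fold; percentile 15.4) and -0.15 in dividing cells.

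The lists of class I antigen presentation and of heat shock lay above the random range in whole libraries, the latter only just. The list of major histocompatibility class I and interferon response had a median of 1.27 (9 measured, 6 higher and 0 lower; percentile 100). HLA-B (ENSG00000234745, chromosome 6, 31269491 to 31357188) had 31.5 and 123 CPM (1.97) and B2M, the shared light chain of class I molecules, 315 and 832 CPM (1.40). HLA-C stood at 1.61, and the HLA genes share similar sequence, so their split is uncertain. The list had 1.15 in astroglia-like cells (5 of 8 higher; HLA-B 1.73, B2M 1.16), 1.51 in glutamatergic-like cells (5 of 6; B2M at 47.7 and 175 CPM, 1.88) and 0.41 in mesenchyme-like cells (6 of 13; HLA-B 2.83, IFITM1 -2.98). In dividing cells it had 0.10 and lay within the random range. The heat shock and dissociation response list had 0.28 in whole libraries (9 measured, 2 higher; percentile 97.7), 0.61 in glutamatergic-like and 0.76 in mesenchyme-like cells, and it lay within the range in astroglia-like (0.12) and dividing cells (0.20). Its member HSPA1A, which has the near-identical copy HSPA1B, stood at 2.44 in whole libraries and had 24.9 and 152 CPM (2.61) in glutamatergic-like cells. The immediate early genes had 0.15 (18 measured, 5 higher and 1 lower; percentile 94.1), 0.66 in glutamatergic-like cells (7 of 17 higher, 2 lower) and 1.06 in mesenchyme-like cells (10 of 17 higher). Among them in glutamatergic-like cells were EGR2 (2.20), JUNB (1.99) and NPAS4 (1.97) against NR4A3 (3 UMIs at day 140; -4.66, -6.96 to -3.09) and NR4A2 (-2.62). The heat shock call in whole libraries ended with the mean over cells (0.29) and with brain classes only (0.23).

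The other lists had these medians. The unfolded protein and integrated stress response had -0.02 (17 measured; percentile 45.6), 0.25 in astroglia-like cells and -0.50 in mesenchyme-like cells, where the cystine transporter SLC7A11 stood at -4.59. The list of p53 targets and apoptosis had 0.16 (12 measured; percentile 93.2), with GADD45B at 2.02 and PHLDA3 at 1.02. Extracellular matrix genes had 0.22 (19 measured, 1 higher; percentile 99.1), with the brain proteoglycan BCAN at 1.44, and -0.81 in dividing cells. With classes weighted equally the extracellular matrix median was -0.13, with the mean over cells -0.05 and with brain classes only 0.08. The Notch signalling list had 0.12 (12 measured; percentile 85.8), with the ligands JAG1 at 1.51 and DLL1 at 1.36, and 0.50 in dividing cells. The WNT and BMP signalling list had -0.19 (9 measured; percentile 5.9), -0.84 in astroglia-like cells (6 of 12 lower) and -1.46 in dividing cells (6 of 9 lower). RSPO3, a secreted WNT enhancer of the cortical hem, had 44.5 and 0.347 CPM (2 UMIs; -7.00, -10.05 to -5.13) in astroglia-like cells, with RSPO2 at -4.37 (3 UMIs; -6.69 to -2.76) and WNT7B at -3.01.

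The list of regional identity, telencephalon, had -0.31 (9 measured, 3 higher and 2 lower; percentile 0.585), with DLX1 at 7.69 and DLX2 at 7.06 against EMX1 at -3.50 and LHX2 at -1.76. It had 0.05 with classes weighted equally and -0.04 with brain classes only. That of regional identity, diencephalon to hindbrain, had -0.95 (3 measured, 1 lower; percentile 1.06), led by ZIC1 (-2.21), and -0.39 and within the random range with classes weighted equally. In mesenchyme-like cells it had 1.57, with HOXB3 at 4.91 (1 UMI at day 93; 2.34 to 10.26) and ZIC1 at -3.90. The gap junctions list had 0.11 (3 measured; percentile 72.2), 0.96 in dividing cells, where GJA1 stood at 5.97 (1 UMI at day 93; 3.47 to 11.28), and -0.89 in mesenchyme-like cells.

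**Figure D3:**
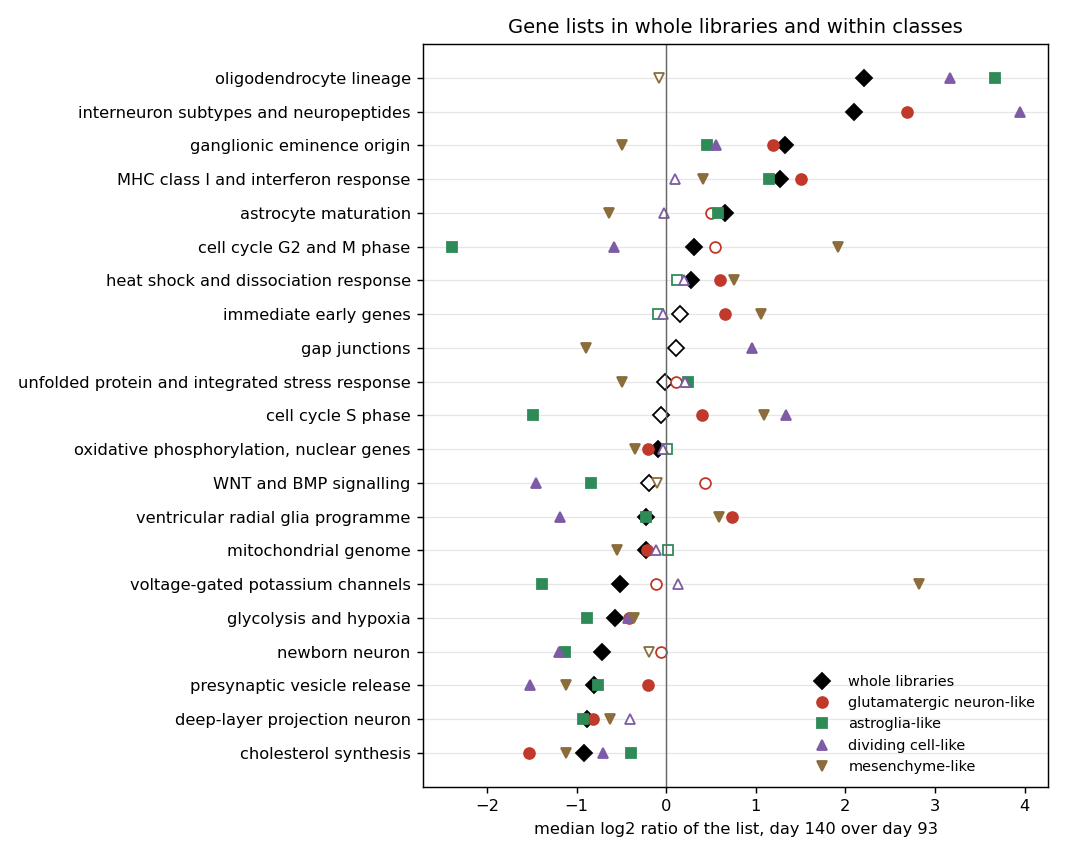
Median log2 ratio, day 140 over day 93, of the 21 gene lists beyond the random range in at least 2 compared classes, in whole libraries (diamonds) and in each class. Filled symbols lie beyond the central 95% of matched random lists and open symbols within it; cholesterol synthesis and glycolysis and hypoxia lie below 0 in every class.

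Of 4532 genes with at least 20 CPM in either library in each compared class, 13 were at least 2-fold apart the same way in all 4 classes. NNAT was the furthest. With 0 UMIs at day 140 its log2 ratio was at most -5.93 in astroglia-like, -5.90 in dividing and -7.24 in mesenchyme-like cells, and with 1 UMI it was -7.36 (-12.66 to -4.87) in glutamatergic-like cells. Thinned, NNAT was seen in 4.79% (4.13 to 5.51%) of all day 93 cells and in 0 of 3574 day 140 cells, which allows up to 0.0839%, and at full depth in 7.38% and 0.0506%. The cholesterol gene STARD4, the mitophagy gene BNIP3 and the synaptic calcium sensor gene SYT1 were lower too. SYT1 was lowest in mesenchyme-like cells (-3.28), and RNA of neuron-like cells in the other classes was not tested for it. The heat shock gene HSPA1A (2.25 to 3.28) and the immediate early genes JUNB and BTG2 were higher. IFI16, a DNA sensor of innate immunity, was at 3.09, 4.05, 3.13 and 2.24 in astroglia-like, dividing, glutamatergic-like and mesenchyme-like cells. IFI16, RAB13, TUSC1 and SPECC1 (higher) and MPPED2 (lower) were outside the rule for named genes and are named after their values were seen.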

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

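The differences between classes below were not tested, and each was picked because it was seen. For 8 gene lists the median log2 ratio lay above the central 95% of random lists in 1 or more compared classes and below it in others. Voltage-gated potassium channels had 2.83 in mesenchyme-like cells (3 measured) and -1.38 in astroglia-like cells (7 measured). Ganglionic eminence origin had 0.46 in astroglia-like, 0.56 in dividing and 1.197 in glutamatergic-like cells against -0.49 in mesenchyme-like cells. Astrocyte maturation had 0.58 in astroglia-like and -0.64 in mesenchyme-like cells. The ventricular radial glia programme had 0.73 in glutamatergic-like and 0.59 in mesenchyme-like cells against -0.22 in astroglia-like and -1.19 in dividing cells. Cell cycle S phase had 1.34 in dividing, 0.40 in glutamatergic-like and 1.09 in mesenchyme-like cells against -1.49 in astroglia-like cells. Cell cycle G2 and M phase had 1.92 in mesenchyme-like cells against -2.39 in astroglia-like and -0.59 in dividing cells. The unfolded protein and integrated stress response had 0.25 in astroglia-like and -0.50 in mesenchyme-like cells. Gap junctions had 0.96 in dividing (3 measured) and -0.89 in mesenchyme-like cells (4 measured).

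Barcodes over the mitochondrial ceiling, 1541 at day 93 and 283 at day 140 with medians of 1796 and 1620 UMIs, were not among the kept cells that the comparisons rest on. Marker sets with at least 50 UMIs in them were set against the kept cells in CPM of non-mitochondrial UMIs, where 0 UMIs allow up to 1.27 CPM at day 93 and 5.15 at day 140. At day 93 choroid plexus markers were at 5072 CPM against 1266 in kept cells, a ratio of 4.01. Epithelium markers (65 UMIs) were at 27.5 against 7.01, a ratio of 3.93, and Cajal-Retzius cell markers at 52.5 against 25.6, a ratio of 2.05. At day 140 pigment cell markers were at 2305 against 248, a ratio of 9.30, and choroid plexus markers at 2331 against 649, a ratio of 3.59. Retina markers there were at 158 against 44.9, a ratio of 3.51, and astrocyte markers at 2875 against 1382, a ratio of 2.08. The shares of these classes among kept cells thus leave out barcodes in which their markers were enriched.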

How the results depend on the processing

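No paired analysis was possible because each day has 1 library, so the groups share only 1 replicate number and no result comes from a test. Chosen after seeing the data were brain classes only, the ceiling of 10% mitochondrial UMIs for lists and within classes, and the glutamatergic-like cells without their shallow cluster. The cause of a shift was not tested. In the 9 alternatives fixed beforehand the GABAergic-like share stayed higher at day 140 (29.01 to 52.1 points) and the glutamatergic-like (-30.8 to -17.8), intermediate progenitor-like and retina-like shares stayed lower. The astroglia-like share had no stable direction. Of 90 values of class shares, 33 moved beyond their interval and 1 reversed. The differences that moved, in points, follow by setting. With a ceiling of 10% they were 52.1 for GABAergic-like, -30.8 for glutamatergic-like, -8.60 for retina-like, -4.35 for astroglia-like, 1.69 for mesenchyme-like, 0.293 for epithelium-like and 0.178 for dividing cells, and 0 for choroid plexus-like and pigment cell-like cells, which were then named in neither library. At that ceiling 1676 of 3200 day 140 cells were GABAergic-like, in place of 1495 of 3954, and 162 were dividing, in place of 514. Cells were thus also named otherwise there and not only left out. With at least 1000 genes per cell the astroglia-like difference was 7.36, and with doublets kept the retina-like one was -9.00. At resolution 0.4 they were 2.06 for astroglia-like, 6.78 for dividing and -9.07 for intermediate progenitor-like cells, and at resolution 1.6 -7.76 for retina-like cells. With genes centred within each library they were 1.56, 6.76 and -5.41 for the same 3 classes and -7.79 for retina-like cells. With each library clustered alone they were 29.01 for GABAergic-like, -17.8 for glutamatergic-like, -9.08 for intermediate progenitor-like and -3.64 for retina-like cells, and the dividing difference reversed to -1.86. With a class per cell they were -23.8 for glutamatergic-like, -11.6 for intermediate progenitor-like, 2.95 for dividing, 1.38 for pigment cell-like and -1.04 for choroid plexus-like cells. Thinned before clustering they were 35.6 for GABAergic-like, -12.6 for astroglia-like, -9.51 for intermediate progenitor-like, 2.96 for dividing and -1.19 for choroid plexus-like cells.

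Counts of genes stayed within 1.5 times in 43 of 48 values fixed beforehand and 12 of 12 added ones. With a floor of 5 CPM 569 genes were higher and 581 lower in whole libraries, with 50 CPM 115 and 124, since the floor sets how many genes are counted, and with a class per cell 98 were lower in astroglia-like cells. With members from 1 CPM, 11 lists were below the random range in glutamatergic-like cells and 5 above it in mesenchyme-like cells. Of 566 list medians fixed beforehand 59 moved and 10 reversed, and of 246 added ones 27 moved. With equal weight for each of the 4 compared classes, the reversed medians were 0.37 for inward rectifier and two-pore potassium channels, 0.23 for voltage-gated calcium channels, 0.17 for postsynaptic scaffold and adhesion, 0.17 for upper-layer projection neuron, -0.65 for cell cycle G2 and M phase, -0.13 for extracellular matrix and 0.049 for regional identity, telencephalon. Extracellular matrix was -0.054 with the mean over cells. With members from 1 CPM, inward rectifier and two-pore potassium channels were -0.71 in glutamatergic-like cells and voltage-gated calcium channels -0.66 in mesenchyme-like cells. In whole libraries, presynaptic vesicle release (-0.88 to -0.42), ganglionic eminence origin (0.69 to 2.24), astrocyte maturation (0.30 to 0.65), glycolysis and hypoxia (-0.85 to -0.51), cholesterol synthesis (-1.06 to -0.91) and major histocompatibility class I and interferon response (0.98 to 1.32) stayed beyond the random range in every alternative run. No named gene reversed. Of 336 of their ratios fixed beforehand 46 moved (17 with a ceiling of 10%, 15 with the mean over cells and 11 with a class per cell), and of 84 added ones 36, with 19 of 24 for brain classes only. With brain classes only PDE6H came within 2-fold, while AMBP had only a lower bound, which was under 2-fold and leaves its ratio open. Of 250 shares of cells with a UMI, 109 moved at full depth, which sets such shares.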

Other observations

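Chosen after the results were seen were the tests of free RNA, of libraries per day and of class shares, and the intervals, directions and counts by class for imprinted genes; those of left-out barcodes, the mitochondrial ceiling, the shallow cluster, imprinted genes in whole libraries and BLCAP were written before their results were seen.

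The 24 marker sets had these values in whole libraries, beside the GABAergic neuron markers (7.37, 11 of 11 higher). Skeletal muscle markers had a median log2 ratio of 7.25 (4 of 9 measured, 4 at least 2-fold higher), with DES at 9.99 and the troponin gene TNNI1 at 7.54. No cluster was named skeletal muscle, and 1583 of the 1868 day 140 UMIs of DES lay in mesenchyme-like cells. Pericyte or smooth muscle markers had 3.101 (5 of 7 higher), with TAGLN at 3.101 and ACTA2 at 3.07. Epithelium markers had 6.38 (5 of 5 higher), with the keratin gene KRT18 at 6.38 and EPCAM at 3.84, and pigment cell markers 7.08 (2 of 3 higher), with the melanosome gene PMEL at 7.94. Oligodendrocyte precursor markers had 2.21 (4 of 5 higher), while of the oligodendrocyte markers CNP stood at 0.31. Astrocyte markers had 0.26 (3 of 11 higher), fibroblast or mesenchyme markers 0.22 (1 of 9 higher) and dividing cell markers 0.35 (1 of 11 higher). Lower were the markers of retina (-2.89, 5 of 5 lower), of glutamatergic neurons (-1.69, 6 of 11 lower), of intermediate progenitors (-1.45, 5 of 8 lower), of neurons of any transmitter (-0.68, 4 of 12 lower) and of radial glia (-0.34, 3 of 12 lower and 2 higher). Outer radial glia markers had -0.07 (1 of 7 higher).

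Microglia or macrophage markers, the immune cells of the brain, had 8 UMIs at day 93 and 51 at day 140 (0.346 and 2.37 CPM of non-mitochondrial UMIs of kept cells), and 0 members were measured. Multiciliated cell, pluripotent cell and monoaminergic or cholinergic neuron markers also had 0 measured members. Of the endothelium markers CLDN5 stood at -0.89 and EGFL7 at -0.66, of the choroid plexus markers OTX2 at -1.97 and TTR at -0.94, of the neural crest or Schwann markers S100B at -0.46, and of the Cajal-Retzius cell markers CALB2 at 5.50 and RELN at -1.18. Among interneuron factors LHX6, which marks cells of the medial ganglionic eminence, was seen in 0 of 3865 thinned day 93 cells and 0 of 3574 day 140 cells, which allows up to 0.0776% and 0.0839% of cells with a UMI at that depth, and at full depth in 0.0233% and 0.0759%. NKX2-1, which acts before it, was seen in 0 and in 1 thinned cell (0.028%), and at full depth in 0% and 0.0253%.

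The GABAergic neuron-like share was 0.210% at day 93 and 37.8% at day 140, and GAD2 was also higher in astroglia-like and dividing cells. Cells lost to the filters at day 93 are argued against, since GABAergic markers in the 1877 left-out barcodes were at 46.7 CPM of non-mitochondrial UMIs, 2.21% of the 2110 CPM in kept day 140 cells. Free RNA alone is argued against for the astroglia-like cells, where the share of thinned day 140 cells with a GAD2 UMI was 10.9 times that in glutamatergic-like cells. The limit for this comparison was set with the shares known. Doublets of astroglia-like and GABAergic-like cells are not covered by it and stay open. With 1 library per day, culture time and another difference between the libraries, such as the organoids taken, cannot be told apart, and either may account for the share.

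The cholesterol synthesis median was lower at day 140 in each of the 4 compared classes. Damaged cells with a high mitochondrial share are argued against as the cause, since with a ceiling of 10% the median stayed below the random range in 4 of 4 classes. The shallow glutamatergic-like cluster is argued against for that class, whose median was -1.53 without it. Culture time stays open, and so does any difference between the libraries in medium or handling, which may act on these genes and was not tested.

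NNAT was lower in each compared class. The test of class shares could not come out otherwise, since NNAT was picked as lower within each class. Its values show only that shares of the compared classes do not account for the whole-library ratio. The ratio nearest to 0 was a bound of at most -5.90, in dividing cells, and the interval in glutamatergic-like cells reached -4.87. A general change of imprinted genes by 2-fold or more is argued against for whole libraries, and smaller changes were not counted. Of 20 other measured imprinted genes, 2 were at least 2-fold higher in whole libraries (DLK1 at 4.20 and DLX5 at 7.53, 10%, 1.23 to 31.7%) and 0 lower, against the 50% set beforehand for this explanation. By class 0 of 20 were lower in glutamatergic-like cells, 1 of 20 in astroglia-like and in dividing cells and 2 of 19 in mesenchyme-like cells (up to 33.1%), while 3, 4, 2 and 5 were higher, and the lowest ratio in any class was -1.70. Counted either way, 7 of 19 (36.8%, 16.3 to 61.6%) differed in mesenchyme-like cells. That interval includes 50%, so a general change stays open for that class. The list of imprinted genes was written after NNAT had been seen, with the ratio of DLX5 known. UMIs counted for BLCAP, whose intron holds NNAT, were not decided by the limits set beforehand. BLCAP (85.7 and 92.4 CPM) gained 10.7% of what NNAT lost. This was short of the 50% set for this explanation and just over the 10% set against it. The gain covers only a small part of the loss. A change in the line or the culture between the days may also account for the lower NNAT level.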
